A study of Eurytemora affinis with 12 samples.

How the data were processed

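RNA was measured in 12 pools of whole adult copepods of the species Eurytemora affinis, a small estuarine crustacean. Each pool held 30 animals of 1 sex, and 3 pools were made for each combination of sex (male or female) and condition (control or copper). Per the labels' protocols, animals were held at 15 °C and a salinity of 15 psu with 18 h of light and 6 h of dark, and copper animals then spent 72 h in water with 25 µg/L of copper. Per the labels' protocols, total RNA was extracted from the pools and made into libraries with an mRNA-seq kit. The same protocols give the water of the copper exposure as acidified at 0.2% and the control water at 0.02%. Whether these percentages differ in fact or through a slip of the decimal point was not given, so copper and acid cannot be told apart if both are right.

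The deposited table holds raw read counts per gene, without normalization, for 23728 gene identifiers, of which 23697 have the LOC form of NCBI and 31 carry tRNA names. Per the submitters' processing notes the tools were FastQC, Trimmomatic, STAR, featureCounts and DESeq2. Their versions, their settings, the use of strand, the genome build and the annotation are not given in the sources used here. The files do not pair the LOC identifiers with gene names, and no reference was used here. For that reason 23 gene lists fixed before the data were examined (among them metal handling, antioxidant enzymes, heat shock proteins, yolk proteins and sperm proteins) could not be filled, and no list was tested. Reads shared between near-identical copies of a gene could not be looked at for the same reason. Per the rule fixed for that case, each comparison names at most 2 identifiers with a positive and 2 with a negative fold change, those with the smallest p. A gene outside this rule is named only where an alternative called few genes, and the text then says that it was chosen after its values were seen.

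The column headers of the table give the group but no replicate number. Each column was therefore used as 1 library of its group, and the letters A, B and C follow column order as names only. The labels describe the pools as biological replicates. No pair of columns was identical. Within groups the chi-square of a library pair per degree of freedom ran from 5.22 to 60.0, so no pair agreed within sampling noise, and all 12 libraries were kept. Total counts per library ran from 8044338 to 16972290. At these depths 1 read was worth 0.0589 to 0.124 CPM, the reads of a gene scaled to the library total, and a gene with 0 reads in a library is compatible with up to 3 counts. Intervals and floors cover counting error only.

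Genes were kept by the filterByExpr rule of edgeR (18579 genes, 78.3% of the table) and libraries were scaled by TMM. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, in 1 fit of 4 group means over all 12 libraries, with Benjamini-Hochberg adjusted p under 0.05 and no fold minimum. The contrasts were copper against control within males, the same within females, the mean of both, their difference (the interaction) and female against male in controls. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Levels are TMM-scaled CPM unless stated, as mean ± SD over 3 libraries. Where a group had 1 to 3 reads, the ratio is given with an exact binomial (Clopper-Pearson) 95% interval of the summed reads. Principal components were computed on log2 CPM with a prior count of 1.

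Alternatives fixed before the data were examined were median-of-ratios and upper-quartile scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), no low-count filter, a filter of at least 5 CPM in at least 3 libraries, fits of only the groups compared, an adjusted p under 0.01, a log2 fold minimum of 1, and leaving out each library in turn. Chosen after seeing the data were robust empirical Bayes in edgeR, limma-voom with sample quality weights, and fits without libraries that stood apart from their group. The edgeR and DESeq2 steps were tested on simulated counts with the means and library sizes of these libraries, in 5 draws of 18579 genes with 200 changed genes each. The changed genes were drawn only from genes with an average log2 CPM above 1. Counts were drawn independently around the group means, with no library set apart from its group. The values that follow need not hold for genes at lower levels, or where a library stands apart. For copper in males edgeR recovered 81.2% of genes changed 4-fold and 23.4% of those changed 2-fold, with 4.60 false calls per draw, and for copper in females 78.2% and 25.2% with 4.80. DESeq2 recovered 88.4% and 45.2% in males with 26.8 false calls per draw, and 85.2% and 47.0% in females with 27.6. Figures were drawn with matplotlib. The microbiota named in the title of the series was not analysed here.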

Results

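Gene expression was measured by mRNA sequencing in whole adults of the copepod Eurytemora affinis, a small crustacean of estuaries, to compare animals held in water with added copper with controls in each sex. Copper was given in the water at 25 µg/L for 72 h. The 4 groups were control males, copper males, control females and copper females, with 3 libraries each, and each library came from a pool of 30 animals. Control males had 9012832 ± 988863 counts per library (SD, n = 3), copper males 10848187 ± 1575976, control females 15248645 ± 1651946 and copper females 15888478 ± 956648. Each female library was thus deeper than every male library, and low male levels rest on fewer reads. Per the labels the copper water was acidified at 0.2% and the control water at 0.02%, so the copper contrasts below hold that stated difference as well. Genes are given by the identifiers of the deposited table, which does not pair them with names.

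Sex set the main structure of the data. The first principal component held 86.2% of the variance of log2 CPM and separated all 6 male from all 6 female libraries, while the second held 3.01%. Copper male library C lay apart from the other male libraries on both. The 143 genes limited to females (at least 20 CPM in control females and no more than a 100th of that level in control males) had a median of 21.0% of their control female level in that library, against 0.485% or less in each of the other 5 male libraries. Its 429 male-limited genes, defined in the mirrored way, had a median of 85.0% of the control male level. Male-limited genes had medians of 0.338% of the control male level in control female library C and 0.543% in copper female library C, and 0.0113% or less in each of the other 4 female libraries.

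**Figure D1:**
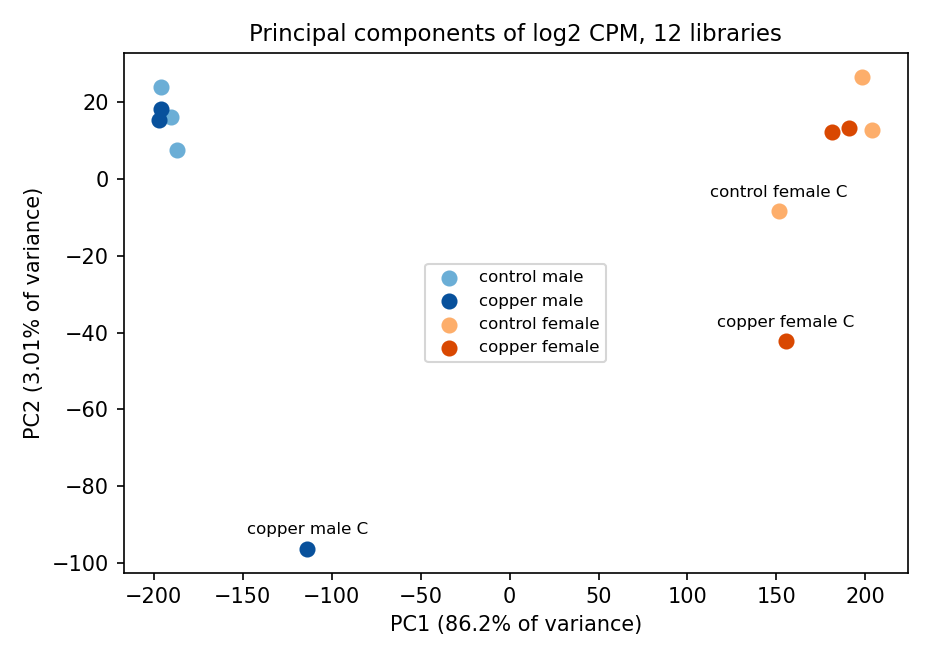
First against second principal component of log2 CPM (arbitrary units), 1 point per library, coloured by sex and condition. Male libraries lie left and female libraries right along the component with 86.2% of the variance, control and copper points of a sex are intermixed, and copper male library C lies apart.

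**Figure D2:**
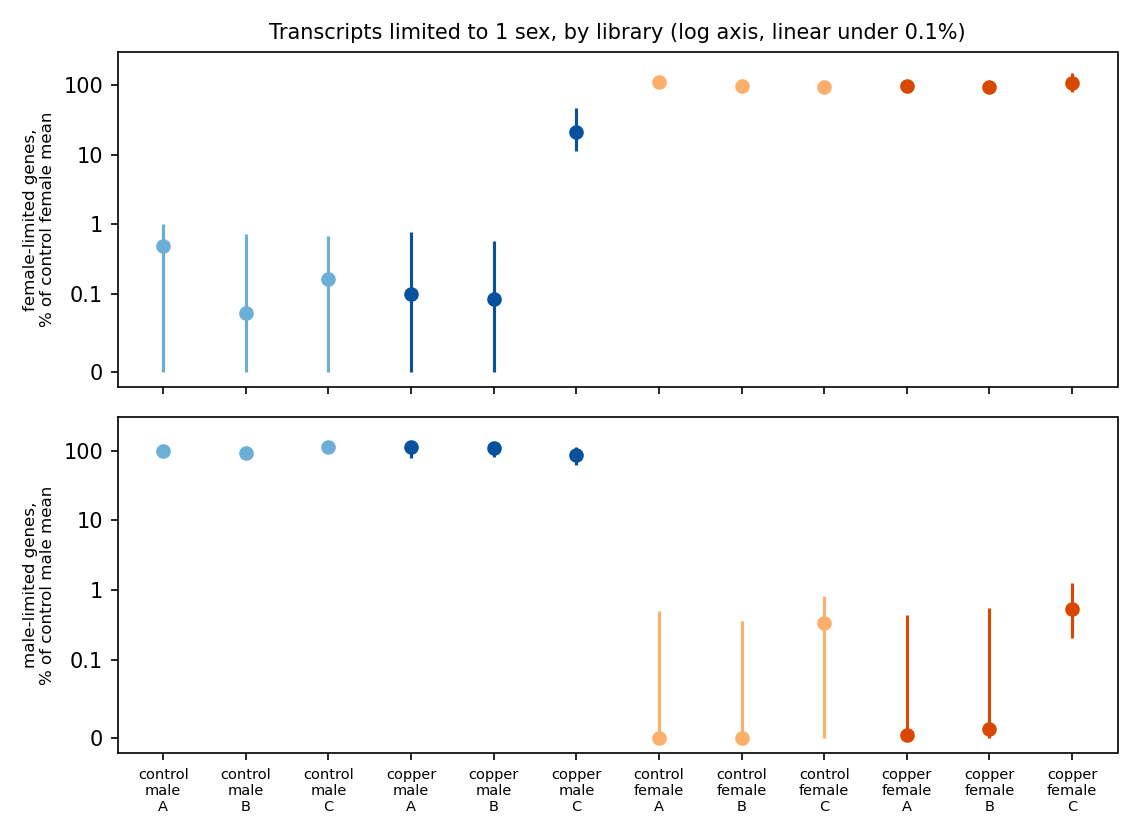
Level of 143 female-limited genes (upper panel, percent of the control female mean) and 429 male-limited genes (lower panel, percent of the control male mean) in each library, as median (point) and 10th to 90th percentile (line), on an axis that is logarithmic above 0.1%. Copper male library C has a female-limited median of 21.0%.

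The comparison of control females with control males asked which transcripts differ with sex. Of the 18579 genes tested, 15521 (83.5%) differed, 6831 of them higher in females and 8690 higher in males (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Large differences were mostly on the male side, since 619 genes were over 100-fold higher in males and 188 in females by fitted fold change. With 161 male-higher genes at 0 reads in all control females and 73 female-higher genes at 0 in all control males set to the floor of 3 counts per library, these counts were 518 and 135. Between 10 and 100-fold lay 1450 genes higher in males and 349 higher in females, with the same floor. The 8196 male-biased genes (past the threshold and over 2-fold) took 58.8% ± 0.598 of the counts in control males (SD, n = 3) and 9.63% ± 1.10 in control females. The 5339 female-biased genes took 53.5% ± 1.31 in control females and 11.3% ± 0.167 in control males. At 20 CPM or more in control females, 12 genes had 0 reads in all 3 control male libraries, where 3 counts amount to 0.299 to 0.373 CPM. The converse held for 43 genes at 20 CPM or more in control males, with 3 counts amounting to 0.181 to 0.224 CPM in the control female libraries.

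The strongest male-biased identifiers by p were LOC111716477, at 98.7 ± 8.55 CPM in control males and 0.733 ± 0.161 CPM in control females (log2 fold change -7.04, SE 0.22, adjusted p = 2.69e-09, edgeR), and LOC111703459, at 216.8 ± 5.82 CPM and 2.03 ± 0.146 CPM (log2 fold change -6.73, SE 0.23, edgeR adjusted p = 3.53e-09). On the female side LOC111697107 had 103.2 ± 3.66 CPM in control females and 18.3 ± 2.48 CPM in control males (log2 fold change 2.49, SE 0.15, edgeR adjusted p = 3.90e-08), and LOC111702945 had 119.3 ± 5.99 CPM and 31.6 ± 1.01 CPM (log2 fold change 1.92, SE 0.12, edgeR adjusted p = 5.41e-08). All 3 libraries of the higher sex lay above all 3 of the other for each of these 4 genes. Male transcriptomes were also more concentrated. The 10 most abundant genes took 9.08% ± 0.849 of the counts in control males and 3.24% ± 0.180 in control females, and 50% of the counts came from 556 ± 28.6 genes in control males and from 1311 ± 30.9 in control females. More genes reached 1 CPM in control males (17052 ± 252) than in control females (14316 ± 426), although male libraries were shallower. The direction of small sex differences depends on the scaling, because the median log2 fold change of all genes was -0.61 under TMM, -0.43 under median-of-ratios factors and -1.09 under upper-quartile factors, a shift of 0.18 and -0.49 from TMM. Under median-of-ratios factors 7276 genes were called higher in females and 8283 higher in males, and under upper-quartile factors 5310 and 9784.

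**Figure D3:**
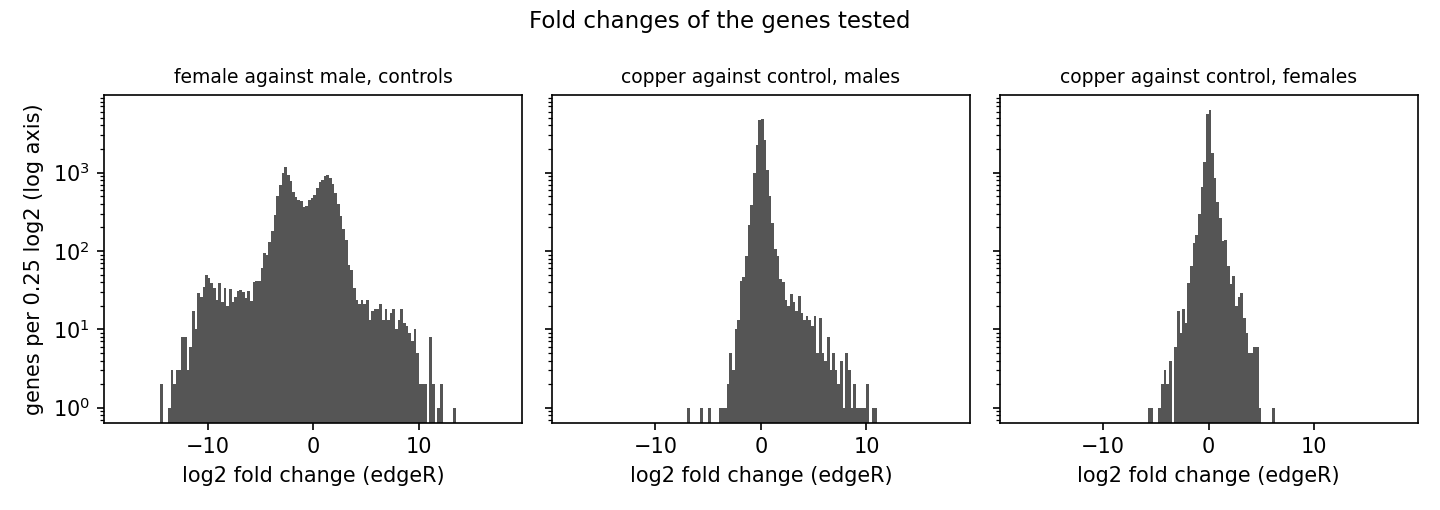
Number of genes (logarithmic axis) per bin of log2 fold change from edgeR, for female against male in controls (left), copper against control in males (middle) and copper against control in females (right), over the 18579 genes tested. The sex contrast has separate male-biased and female-biased peaks, while the copper contrasts peak near 0, with a right tail in males.

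Copper against control in males asked which male transcripts differ after exposure. No gene passed the edgeR threshold, with a smallest adjusted p of 0.358, 1591 genes at an unadjusted p under 0.05 (929 expected by chance, and 1159 to 1769 in the other groupings of the same 6 libraries) and 46 genes called by DESeq2. Of the 1591 genes, 71.2% were higher with copper. Without copper male library C there were 1204 of 19136 genes tested, with 51.4% higher. By smallest p, LOC111712496 had 7.24 ± 2.00 CPM in copper males and 1.97 ± 0.736 CPM in control males (log2 fold change 1.90, SE 0.30, edgeR adjusted p = 0.358). This gene was higher in females, at 17.3 ± 1.65 CPM in controls, and its 3 copper male libraries held 7.10, 5.32 and 9.30 CPM, the last in library C. LOC111714068 had 165.0 ± 2.49 CPM in copper males and 88.5 ± 13.5 CPM in control males (log2 fold change 0.90, SE 0.15, edgeR adjusted p = 0.358). On the lower side, LOC111703021 had 1.59 ± 0.585 CPM in copper males and 5.35 ± 0.838 CPM in control males (log2 fold change -1.74, SE 0.36, edgeR adjusted p = 0.440). LOC111710173 had 1 read over the copper male libraries and 32 over the control male libraries, a ratio of 38.7 with a 95% counting interval of 6.47 to 1576 (edgeR adjusted p = 0.440).

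Of the 46 genes DESeq2 called in males, 36 were higher in copper males, and 33 of these 36 were female-biased in controls, where 28.7% of all genes tested by edgeR were, a difference that was not tested. Without copper male library C, whose female-limited genes had a median of 21.0% of the control female level, DESeq2 called 12 genes, of which 7 were among the 46, while it called 567 genes without copper male library A and 331 without copper male library B. LOC111712496 and LOC111714068 were among the genes DESeq2 called both with and without that library (adjusted p = 0.0136 and 0.00280 without it). LOC111703021 was called with it (DESeq2 log2 fold change -1.75, adjusted p = 0.0102) and not without it, at a similar fold (DESeq2 log2 fold change -1.58, adjusted p = 0.154).

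Copper against control in females asked the same of female transcripts. No gene passed the edgeR threshold, with a smallest adjusted p of 0.708, 598 genes at an unadjusted p under 0.05 (929 expected by chance, and 433 to 1116 in the other groupings of the same 6 libraries) and 11 genes called by DESeq2, 5 higher and 6 lower with copper. LOC111716837 had 18.7 ± 2.88 CPM in copper females and 10.0 ± 0.567 CPM in control females (log2 fold change 0.90, SE 0.15, edgeR adjusted p = 0.708). LOC111698998, a male-biased gene at 64.4 ± 5.30 CPM in control males, had 0.863 ± 0.271 CPM in copper females and 0.204 ± 0.0825 CPM in control females (log2 fold change 2.06, SE 0.41, edgeR adjusted p = 0.949). These levels rest on 45 reads in copper and 10 in control females. Copper female libraries A, B and C had 0.832, 0.608 and 1.15 CPM. In library C, male-limited genes had a median of 0.543% of the control male level. LOC111697772 had 0.699 ± 0.540 CPM in copper females and 4.27 ± 1.31 CPM in control females (log2 fold change -2.58, SE 0.45, edgeR adjusted p = 0.708). LOC111696063 had 3 reads over the copper female libraries and 40 over the control female libraries, a ratio of 13.7 with a 95% counting interval of 4.38 to 69.4 (edgeR adjusted p = 1). Of these 4 genes DESeq2 called LOC111716837 (adjusted p = 0.0110) and LOC111697772 (adjusted p = 2.50e-04). DESeq2 called 30 genes in females, LOC111698998 among them (DESeq2 adjusted p = 0.0477), when copper male library C, which enters the shared fit, was left out. Of the 11 genes called by DESeq2, 10 were male-biased in controls, 5 of them higher and 5 lower with copper, where 44.1% of all genes tested by edgeR were male-biased, a difference that was not tested. Genes whose copper and control libraries did not overlap made up 7.85% of those tested in females and 10.8% in males, where chance gives 10%.

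The average copper effect over both sexes asked which genes differ with copper irrespective of sex. The lowest p fell on 4 genes that differed by similar folds in males and in females, although none passed the edgeR threshold. LOC111696271 had 18.2 ± 1.90 CPM in copper males against 4.20 ± 2.38 CPM in control males, and 3.89 ± 0.397 CPM in copper females against 1.01 ± 0.595 CPM in control females (average log2 fold change 2.03, SE 0.32, edgeR adjusted p = 0.210). LOC111716837 had 74.2 ± 6.86 CPM in copper males against 47.5 ± 1.22 CPM in control males, and in females the values given above (average log2 fold change 0.77, SE 0.11, edgeR adjusted p = 0.142). LOC111707955 had 19.8 ± 4.11 CPM in copper males against 39.2 ± 1.67 CPM in control males, and 3.11 ± 0.459 CPM in copper females against 5.79 ± 1.10 CPM in control females (average log2 fold change -0.94, SE 0.16, edgeR adjusted p = 0.255). LOC111703052 had 25.3 ± 2.70 CPM against 50.04 ± 4.05 CPM in males and 3.94 ± 0.573 CPM against 8.02 ± 2.81 CPM in females (average log2 fold change -1.002, SE 0.17, edgeR adjusted p = 0.255). For each of these 4 genes the copper and control libraries did not overlap in either sex, which their choice by smallest p favours, and each was higher in males than in females, by 4.18-fold to 6.76-fold in controls.

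**Figure D4:**
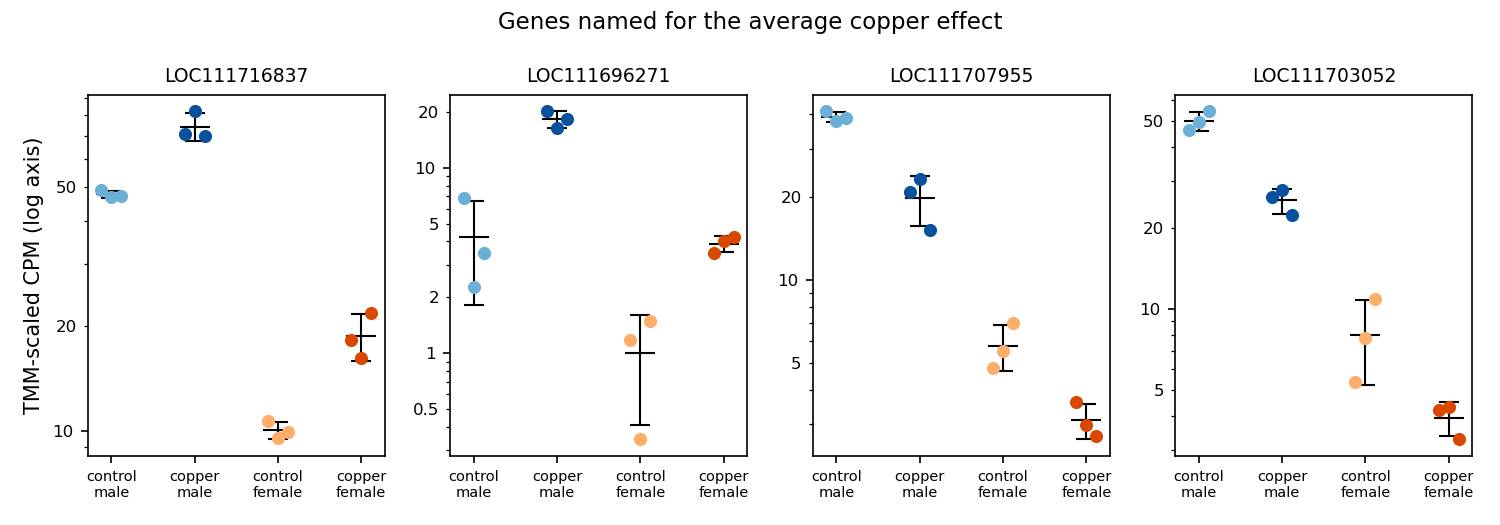
TMM-scaled CPM (logarithmic axis) of the 4 genes with the smallest p for the average copper effect, as points per library with the mean and SD (n = 3) of each group. LOC111716837 and LOC111696271 are higher and LOC111707955 and LOC111703052 lower in every copper library than in every control library of the same sex, and their edgeR adjusted p lay between 0.142 and 0.255.

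In the average contrast 1282 genes had an unadjusted p under 0.05 in edgeR, 64.8% of them higher with copper, where 929 are expected by chance. There were 1204 without copper male library C, with 52.6% higher. DESeq2 called 55 genes, 25 higher and 30 lower, of which 38 were male-biased and 13 female-biased in controls, and all 4 genes named above were among them. Of all genes tested by edgeR, 44.1% were male-biased and 28.7% female-biased, and the difference from these shares was not tested. Without copper male library C DESeq2 called 46 genes, of which 31 were among the 55. Across genes, which are not independent replicates, the male and female log2 fold changes had a Pearson r of 0.0437 and a Spearman rho of 0.112. In both sexes 65 genes had an unadjusted edgeR p under 0.05, where 51.2 are expected for independent lists. Of these, 55 (84.6%) had the same sign in males and females, a share that was not counted over other groupings. The calls of edgeR shared no gene between the sexes, as there were 0 in each. DESeq2 called 1 gene higher with copper in both sexes, LOC111696271, where 0.00807 are expected for independent lists (Fisher's exact test, two-sided, p = 0.00804), and 0 lower in both. That p takes genes as independent, and both lists came from 1 fit that shares each gene's estimate of spread. It is therefore no measure of a shared response. Other groupings of the libraries gave lists as long in each sex, and the overlap was not counted over them.

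The interaction asked whether the copper effect differs between females and males. No gene passed the edgeR threshold, with a smallest adjusted p of 1.00, 889 genes at an unadjusted p under 0.05 (929 expected by chance) and 11 genes called by DESeq2. Among genes with a more positive copper effect in females, the smallest p values belonged to LOC111710173, which had 32 reads in control and 1 in copper males but 29 and 58 in females, and LOC111703439, which had 34 and 12 reads in males and 1 and 18 in females (edgeR adjusted p = 1.00 for each). The female ratio of LOC111703439 was 17.5 with a 95% counting interval of 2.76 to 728. In the other direction, the log2 fold change of LOC111712496 was 1.90 in males and -0.17 in females, and that of LOC111697772 was 0.30 in males and -2.58 in females (edgeR adjusted p = 1.00 for each). Of the 11 genes called by DESeq2, 10 were female-biased in controls, and 8 had 0 reads in all control male libraries, so that their fitted interaction is no estimate of a fold. For 7 of these the male reads were all in copper male library C, and without that library DESeq2 called 0.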

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

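No paired analysis was possible because the columns of the count table carry no replicate numbers, and the alternatives planned for the gene lists were not run because the lists could not be filled. The count of genes that differed between the sexes in controls stayed within 1.5 times its value of 15521 under every alternative run, from 12086 to 16063 genes (14915 to 15917 with 1 library left out). Calls for copper depended on the tool and on single libraries. DESeq2 called 46 genes in males, 11 in females, 55 for the average effect and 11 for the interaction, with 1 gene shared by the sexes, where edgeR and limma-voom called 0 of each. With 1 library left out, edgeR called 0 to 1 genes in males, 0 to 1 for the average and 0 to 1 for the interaction. Each 1 came without copper male library A and was LOC111715860 (chosen after its values were seen), a gene at 49.99 CPM in control females, 0.400 CPM in control males and 5.11 CPM in copper males. These means are over all libraries of a group, copper male library A included. The fits that follow were chosen after seeing the data. Without copper male library C, DESeq2 called 12 genes in males, 30 in females, 46 for the average effect and 0 for the interaction, with 1 shared by the sexes. Without copper male library A it called 567 in males, and without copper male library B 331. Sample quality weights in limma-voom, lowest for copper male library C (0.198), gave 1 gene in males (LOC111714068), 1 in females (LOC111697772) and 13 for the average effect, of which 12 were among the 55 of DESeq2. Without copper male library C and both female libraries C, edgeR called 1 gene in females, LOC111697772. A fit of males alone without copper male library C called 1, LOC111702131 (chosen after its values were seen), at a log2 fold change of -1.43. Over all libraries of a group, library C included, its means were 95.1 CPM in control males and 37.3 CPM in copper males. Apart from the male and interaction calls of DESeq2, of which 15.2% and 0% stayed without copper male library C, the cause was not tested. All other alternatives run gave 0 calls for copper. The named genes kept their direction under every alternative run that gave them a value. Depth limits LOC111710173, LOC111696063 and LOC111703439, which rest on 1 to 3 reads in 1 group, and LOC111698998, with 10 reads in control females.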

Other observations

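The tests of library C, of the DESeq2 calls in males and of male-limited transcripts in females were chosen after the results they bear on were seen, as were the splits of the genes at an unadjusted p in each sex, while the other counts over splits of the libraries were planned before those counts were seen.

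Genes with a sex bias took different positions in the copper contrasts of males and females. In males the 5339 female-biased genes had a median log2 fold change with copper of 0.26, and 80.8% of them were higher with copper, whereas the 8196 male-biased genes had a median of -0.12 with 35.8% higher. Without copper male library C the medians were 0.02 for female-biased and 0.02 for male-biased genes, with 52.9% and 52.7% higher. In females the female-biased genes had a median of -0.0011 with 49.6% higher, and the male-biased genes a median of 0.09 with 57.7% higher. These female values moved as well without copper male library C, which enters the shared scaling and fit, to -0.03 with 40.03% higher and to 0.06 with 55.4% higher. The classes were set on the control libraries, which also enter these contrasts, so part of any shift can come from the shared controls, and the class medians were not tested. In total 130 genes did not overlap between copper and control libraries in both sexes in the same direction, 59 higher and 71 lower, and 55 did so in opposite directions. For independent libraries 92.9 are expected of each, at a chance share of 10% in each sex and even directions. The observed shares were 10.8% in males and 7.85% in females, so 92.9 is not the number expected at those shares.

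Copper male library C carried transcripts limited to females at a median of 21.0% of the control female level. A response of males to copper would put such transcripts in the other copper male libraries too, and the higher of their medians was 0.101%, below the highest control male library at 0.485%. A whole library of females under a male label would lack male-limited transcripts, and their median was 85.0% of the control male level. A candidate explanation that stays open is female RNA in the pool, since female-limited genes gave a mixing share of 21.1% (middle 80% of genes 11.7% to 41.8%), male-limited genes gave 18.1% (middle 80% from -7.78% to 40.2%, which includes 0), and a mix of the other male libraries with female libraries predicted 59.5% of the variance of the library's log2 deviations over 15399 genes. The tables do not tell whether such RNA would have come from female animals or from handling, nor does the mix predict the rest of the variance.

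DESeq2 called 46 genes for copper in males where edgeR called 0. Only 15.2% of them stayed past the threshold without copper male library C, whereas 100% stayed without copper male library A and 95.7% without copper male library B. These values are consistent with most of the calls depending on library C, but not with that library making all of the fold changes. Of the 39 genes lost without it, 32 kept their direction, their median log2 fold change in the called direction went from 1.75 (quartiles 1.03 and 6.90) to 0.91 (quartiles 0.61 and 1.38), and 12 fell under 50% of their former log2 fold change. The 7 genes called with and without that library, LOC111712496 and LOC111714068 among them, are not accounted for by it.

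Male-limited transcripts lay at medians of 0.338% and 0.543% of the control male level in control and copper female libraries C. Reads cross-assigned evenly between libraries would raise the other 4 female libraries alike, and summed over the 429 genes the highest level there was 0.0444%, which is 13.1% of the lower of the libraries C. A trace of male RNA in these pools and uneven cross-assignment both stay open as candidate explanations. Male-limited genes with at least 1 read reached 91.1% of the number predicted from 1 mixing share in the control library, but that share was taken from the same genes, so this value could not have argued against it. Sperm or spermatophores carried by mated females would give a different set of male transcripts from whole males, and with no gene names this biological explanation was not tested.

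Splits drawn within both sexes at once did not exclude chance for the values in this paragraph that lie above 0. For the 0 genes edgeR called for the average effect and for the interaction the splits say nothing, since any split reaches 0 (100 of 100 for each, highest other 2 for each). The 1282 genes at an unadjusted p under 0.05 for the average effect were reached in 36 of 100 splits (highest other 2018). The 55 DESeq2 calls for the average effect were reached in 15 of 40 splits (highest other 90), and the 11 for the interaction in 33 of 40 (highest other 190). For the average effect, splits with both female libraries C on the same side called 38 to 90 genes. Other splits that kept them apart, as the real groups do, called 6 to 37 and, at the highest, 64. The share of splits that reached 55 thus rests largely on where these libraries fell, and is no clear measure of chance. This pattern was seen after the counts and was not tested. The absolute correlation of male and female mean log2 differences, 0.0810, was reached in 34 of 100 splits (highest other 0.152). This is a different measure from the Pearson r of 0.0437 between edgeR fold changes, which was not run over splits. For genes that did not overlap in both sexes, the larger of the same-direction and opposite-direction counts, 130 in the real groups, was reached in 26 of 100 splits (highest other 270). The same-direction count alone was reached in 11 of 100 (highest other 244).

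Within 1 sex, or between the sexes in controls, 3 against 3 libraries make 10 splits, too few for a share under 0.05. For edgeR the count between the sexes was 15521 (1 of 10 splits, highest other 0), while the counts of 0 in males (highest other 0) and in females (highest other 1) are reached by any split, 10 of 10, and say nothing. The 1591 genes at an unadjusted p under 0.05 in males were reached in 3 of 10 splits (highest other 1769) and the 598 in females in 7 of 10 (highest other 1116). For DESeq2 the 46 genes in males were reached in 6 of 10 splits and the 11 in females in 5 of 10. The other female splits that reached 11 all set both libraries C on the same side, with 174, 132, 117 and 103 calls. The other female splits, which kept them apart as the real groups do, called 1, 0, 0, 0 and 1. This pattern was seen after the counts, so it is no test of copper. Other DESeq2 splits called up to 153 genes in males and 174 in females. In females the high counts went with where both libraries C fell, which is structure among the libraries that does not follow copper. The low counts on the remaining female splits argue against calls that the tool makes on any split. In males such structure and calls of the tool itself were not told apart. On the male split with 153 calls and the female split with 174, edgeR called 0 genes. The split of males with 153 calls set control libraries A and C with copper library C against the rest. That of females with 174 set control libraries A and B with copper library A against control library C with copper libraries B and C.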
